A study of Mus musculus with 6 samples.

How the data were processed

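Total RNA of sorted bone marrow cells was labelled and hybridised to Affymetrix whole-transcript arrays, with 1 array per sample and 6 arrays in all. Groups and replicate numbers were taken from the sample titles, which name 2 biological replicates each for vector, BCR-ABL and BCR-ABL-Blk; the labels do not say how many mice made up a replicate. The mice were of the C57BL/6 strain and 8 weeks old, per the labels. Cells were collected 14 days after transplantation, per the labels' protocols.

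The deposited values are on a log2 scale, with 2 decimals, for 35557 probe sets. Per the submitters' processing notes they were made with Affymetrix Expression Console 1.1 and RMA, a method that corrects background, normalizes and summarises the probes of a set. The options used and the genome build are not given in the sources used here, so no coordinates are printed. RMA as usually run gives every array the same distribution, but the deposited log2 values did not share one: their medians ran from 7.01 to 7.52. The arrays were therefore quantile normalized (limma) before any test was run, a choice made after the distributions and before any comparison were seen. This changes small shifts of whole groups most, and keeps large changes of single genes. The deposited values without normalization between arrays were added as an alternative after seeing the data, as were the other scalings and the leaving out of arrays for gene lists.

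Gene symbols came from the platform annotation given for the probe sets, which can be old. It listed 23410 of 35557 probe sets, of which 21789 had 1 symbol and 1621 several; the other 12147 are unnamed here. By Entrez ID 21698 of the 21789 matched the RefSeq gene table, 91 did not, and 0 symbols were updated. Probe sets with several symbols were not named. For the 999 genes with several probe sets the one with the highest mean over 6 arrays was kept, which left 19938 genes. No filter on level was used, since detection calls were not used here. The median level of the named genes was 7.50, which served the naming rule and is no background level. Signal over background was not measured, so where a group reads low, a fold is that of the measured signal and may understate the change in RNA.

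Group differences were estimated with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) over all 6 arrays and 3 groups, without a block. The fit had 3 residual degrees of freedom, to which the prior added 4.40. P-values are two-sided, Benjamini-Hochberg adjusted over the 19938 genes of a comparison, and called below 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 39 lists of a comparison. With an estimated correlation camera also rests on the 3 residual degrees of freedom, so a call can be lost where the correlation is low. The estimate was 0.74 for B cell genes and 0.02 for LSK stem cell genes. It was also high for G2/M (0.50), interferon response (0.49), neutrophil granule (0.48), erythroid (0.47) and MHC class II genes (0.45). For genes of mast cells, basophils and eosinophils it was 0.38. The preset correlation of 0.01 overstates the evidence for such lists. Camera compares a list with all other genes; fry tests whether the list moves one way. The lists held 714 entries, of which 641 were measured, and counts of members are given over all genes and adjusted over the list alone. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

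The tests, the 39 lists, most alternatives and the rule for named genes were fixed before the data were examined. By that rule Blk, Pax5, Ebf1, Myc, Cdkn1b, Abl1 and Bcr are always named. Then come, per comparison, the 8 largest rises and 8 largest falls among genes past the threshold whose arrays do not overlap between groups and whose higher group mean is above the median level. Predicted genes, clones, small RNAs, olfactory and vomeronasal receptors and receptor or antibody segments were skipped, and places left over were filled by the smallest unadjusted p, given as not passed. Last come up to 4 members with the smallest p of each described list. A list is described where it passed camera or held at least 3 called members, and cell type and quality lists are given at least as values; other lists with several members changed over the list alone were added to the text afterwards. A few further genes are named where a small count called for it.

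The fit was tested on simulated data for BCR-ABL against vector, in 20 runs of 19938 genes with 200 changed. It recovered 17.9% of genes changed 1.5-fold, 72.9% at 2-fold, 97.7% at 4-fold and 99.7% at 8-fold, and 7% of calls were false. All simulated arrays had the same variance per gene. The measured vector arrays varied more, with array weights of 0.736 against 1.205 for BCR-ABL arrays. These shares hold for the simulated setting and may differ in the data. A planted list of 20 genes shifted by 0.4 was found in 20 of 20 runs, and 0 unchanged lists were called. The simulated genes varied independently, so false calls of lists whose members move together were not checked. B cell genes, with an estimated correlation of 0.74, and neutrophil granule genes, with 0.48, are among such lists. Comparisons that share arrays were set beside 100 simulations with the gene variances drawn from the fit. A first version used the fitted variances themselves and was replaced after its results were seen. In simulations in which Blk has no effect, the 112 genes with an adjusted p under 0.10 kept their measured change against vector.

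Alternatives were other scalings (centring on the median, cyclic loess, none), a filter on dim genes, the average of a gene's probe sets, only the 4 arrays compared, the replicate number as a block, no intensity trend, array weights, an adjusted p under 0.10, a 2-fold threshold, and leaving out each array in turn.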

Results

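Gene expression was measured on 6 whole-transcript Affymetrix arrays of mouse bone marrow cells, with 2 biological replicates in each of 3 groups. Marrow of C57BL/6 donors given fluorouracil was infected with a retrovirus and transplanted into recipients of the same strain. The virus carried GFP alone (vector group), the fusion oncogene BCR-ABL with GFP (BCR-ABL group), or BCR-ABL together with Blk and GFP (BCR-ABL-Blk group). BCR-ABL is the constantly active tyrosine kinase of chronic myeloid leukemia, and Blk is a Src family kinase known mainly from B cells. After 14 days, marrow cells were sorted that were positive for GFP, c-Kit and Sca-1 and negative for lineage markers. This gate (LSK) holds stem cells and multipotent progenitors; the labels call the sorted vector cells hematopoietic stem cells and the others leukemic stem cells. The number of arrays limits the precision: over 19938 genes the median standard error of a difference between groups was 0.129 on the log2 scale.

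The median deposited log2 value was 7.06 and 7.44 on the vector arrays, 7.20 and 7.01 on the BCR-ABL arrays, and 7.52 and 7.29 on the BCR-ABL-Blk arrays. Since these distributions differed within groups, all values below were quantile normalized, unless a sentence names another scaling. Without normalization between arrays, the median gene differed by −0.11 between BCR-ABL and vector, by 0.255 between BCR-ABL-Blk and BCR-ABL, and by 0.15 between BCR-ABL-Blk and vector.

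**Figure D1:**
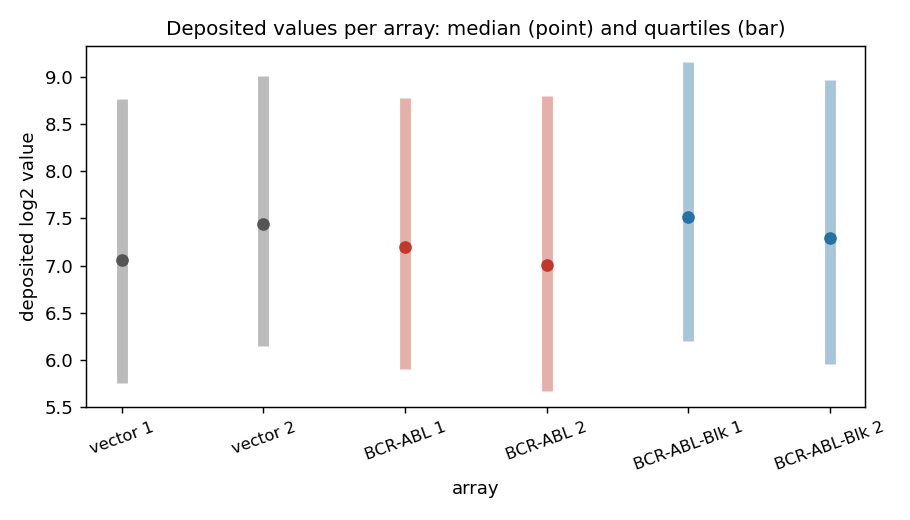
Deposited log2 values on each of the 6 arrays (horizontal axis), with the median over all probe sets as a point and the range from the lower to the upper quartile as a bar. The medians lie between 7.01 and 7.52, and replicates of a group differ as much as groups do.

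Across genes, which are not independent replicates, the BCR-ABL arrays correlated with each other at r = 0.994 and the BCR-ABL-Blk arrays at r = 0.992. The vector arrays correlated less, at r = 0.987, and replicate 1 of BCR-ABL resembled replicate 1 of BCR-ABL-Blk (r = 0.995) more than it resembled its own partner. The first principal component held 41.1% of the variance and set both vector arrays (−13.4 and −32.5) apart from the 4 arrays with BCR-ABL, which lay between 11 and 12.1. The second component (22.1%) separated the vector arrays from each other, at 24.6 and −13.8, and the third (16.9%) set replicate 2 of BCR-ABL-Blk (20.5) apart. Lineage genes differed between the vector replicates: the median B cell gene was 1.37 higher on replicate 1 than on replicate 2, the median erythroid gene 0.61 higher, and the median difference of neutrophil granule genes was −0.61. Within BCR-ABL-Blk, the median gene of mast cells, basophils and eosinophils was 0.65 higher on replicate 1.

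Blk, which the BCR-ABL-Blk virus carries, was examined first as a check on the labels. Its probe set 10420758 read 7.05 ± 0.14 in vector, 6.57 ± 0.04 in BCR-ABL and 6.98 ± 0.04 in BCR-ABL-Blk cells (mean ± SD, n = 2 each). All 3 means lie below the median level of named genes and signal over background was not measured, so this is a weak check. Both BCR-ABL-Blk arrays lay above both BCR-ABL arrays, by 0.41 log2 on average (95% interval 0.155 to 0.663), which did not pass over all genes (limma adjusted p = 0.999). It passed when adjusted over the list alone, a list of 5 genes tied to this study (adjusted p = 0.0317); that list was drawn from what was known of the study and is not independent evidence. Between BCR-ABL-Blk and vector cells the difference was −0.07 (adjusted p = 0.914), and it was 0.03 without vector replicate 1 and 0.08 without normalization between arrays. BCR-ABL cells lay below vector cells by 0.48 on the log2 scale (difference −0.48, SE 0.11, adjusted p = 0.197). The labels do not give the species or form of the transferred Blk sequence, so how much of it this probe set could read is unknown. Against vector, Pax5 and Ebf1, transcription factors of B cell development, gave differences of −1.38 (adjusted p = 0.454) and −2.64 (adjusted p = 0.319) in BCR-ABL cells, and −1.49 (adjusted p = 0.362) and −2.91 (adjusted p = 0.232) in BCR-ABL-Blk cells. Myc differed by 0.01 and Cdkn1b, the inhibitor p27, by 0.08 between BCR-ABL and vector, neither past the test, and other settings turned both signs. The probe sets of Abl1 and Bcr, whose human parts make up the oncogene, differed by −0.20 and −0.14 without passing. Between BCR-ABL-Blk and BCR-ABL, Pax5 differed by −0.10, Ebf1 by −0.27, Myc by −0.08, Cdkn1b by −0.04, Abl1 by 0.21 and Bcr by 0.16, all at an adjusted p of 0.999.

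The comparison of BCR-ABL with vector asked what the oncogene does to gene expression in LSK cells. Akr1c12, an aldo-keto reductase gene, rose most, from 6.92 ± 0.08 in vector to 11.3 ± 0.14 in BCR-ABL cells (SD, n = 2 each), which is 21.1-fold (log2 change 4.40, SE 0.13, adjusted p = 4.3e-05). Its neighbour in sequence Akr1c13 rose 6.51-fold (log2 change 2.70, SE 0.14, adjusted p = 0.00151); the genes are nearly identical paralogs, so the share of each in the signal is uncertain. Gzmb, a serine protease of cytotoxic and mast cell granules, rose 9.53-fold (log2 change 3.25, SE 0.31, adjusted p = 0.0187), and Khdc1a rose by 3.56 (SE 0.39, adjusted p = 0.0311). The vector means of Akr1c12 (6.92), Gzmb (7.22) and Khdc1a (5.30) lay below the median level of named genes, and signal over background was not measured, so these folds are those of the measured signal. Ncam2, an adhesion molecule, Enah, an actin regulator, Itm2a, a membrane protein, and Stk39, a kinase that controls ion cotransport, rose by 2.95, 2.80, 2.42 and 2.16; of these, Ncam2, Itm2a and Stk39 also lay below that level in vector cells. In the other direction, H2-Ab1, a chain of MHC class II, fell by 1.38 (SE 0.14, adjusted p = 0.0206). Cybb, the catalytic subunit of the phagocyte NADPH oxidase, fell by 1.23, Tifab by 1.16 and Cst3, the protease inhibitor cystatin C, by 0.45. Ms4a6b (−0.88), Themis2 (−1.11), Cox6a2 (−1.13) and Naaa, a lysosomal amidase (−1.22), lay just short of the threshold, with adjusted p from 0.0502 to 0.0509. By the naming rule, both arrays of one group lay beyond both arrays of the other for each of these genes, so this is no further evidence. The same held for 37.0% of all genes and holds for 33.3% by chance.

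In all, 24 genes were higher and 5 lower in BCR-ABL than in vector cells at an adjusted p under 0.05; 20 and 4 of these differed at least 2-fold. At an unadjusted p under 0.05 there were 1722 genes, where chance gives 997. Without normalization between arrays 176 genes were higher and 225 lower. Single arrays moved the counts strongly: 345 higher and 157 lower without vector replicate 1, 66 and 143 without vector replicate 2, and 1 and 0 without either BCR-ABL array. Leaving out either BCR-ABL-Blk array, which only lends its spread to this comparison, left 2 lower. Akr1c12 was the gene that still passed without BCR-ABL replicate 1 (4.31, adjusted p = 0.00758) and without replicate 2 (4.46, adjusted p = 0.00551). A lone array in a group was assumed to vary like those of the other groups. Leaving out an array also changed which genes passed, so a similar count does not mean the same genes.

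**Figure D2:**
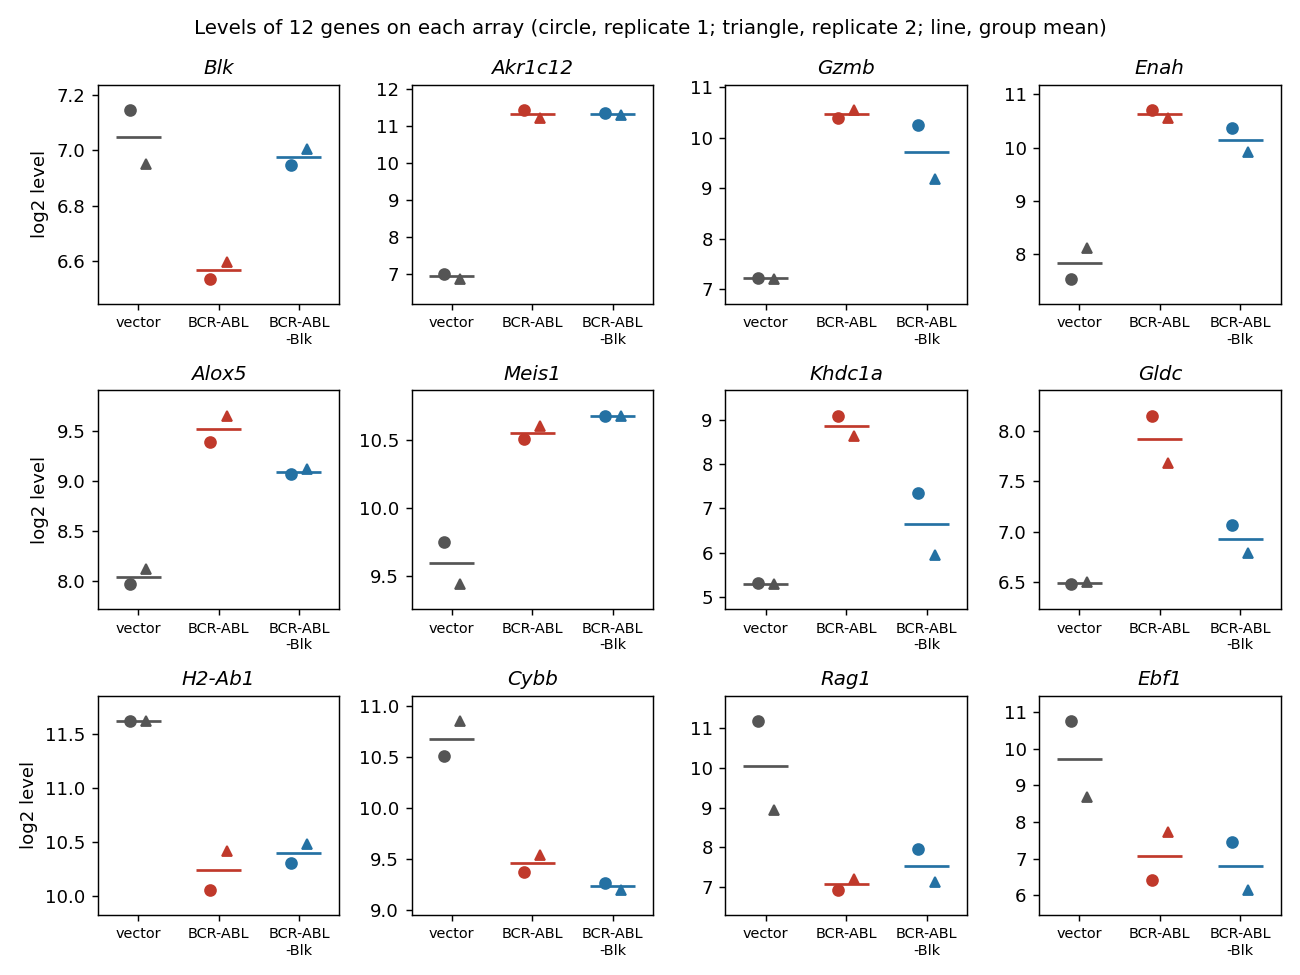
Log2 level (vertical axis) of 12 genes on each array, in 3 groups of 2 along the horizontal axis, with circles for replicate 1, triangles for replicate 2 and a line at the group mean. Akr1c12 lies near 11.3 on the 4 arrays with BCR-ABL and near 6.92 on the vector arrays, while Rag1 and Ebf1 differ widely between the vector replicates.

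B cell, monocyte, dendritic cell, MHC class II and progenitor genes were lower as groups in BCR-ABL than in vector cells by camera with the preset correlation. By fry none of these lists passed (adjusted p from 0.10 to 0.28). Of 20 measured B cell genes, 17 lay below 0 with a median of −1.46 (camera adjusted p = 1.8e-13, and adjusted p = 0.41 with an estimated correlation). None passed over all genes (limma, adjusted p under 0.05) and 14 fell when adjusted over the list alone, among them the adaptor Blnk (−3.20, SE 0.49), the recombinase Rag1 (−2.98, SE 0.64), the polymerase Dntt (−1.78, SE 0.32) and the surrogate light chain Vpreb1 (−1.74, SE 0.33). The median was −0.66 without vector replicate 1 and −2.22 without vector replicate 2. All 17 monocyte and macrophage genes lay below 0 (median −0.75, camera adjusted p = 6.7e-13, and adjusted p = 0.27 with an estimated correlation). Over that list alone 8 fell, led by the transcription factor Irf8 (−1.33), Cx3cr1 (−0.87), F13a1 (−1.59) and Ccr2 (−0.75), with 0 over all genes, and without vector replicate 1 the median was −0.43. Of 16 dendritic cell genes, 7 fell over the list alone, with 0 over all genes (median −0.36, camera adjusted p = 1.6e-11, and adjusted p = 0.27 with an estimated correlation). They included the chemokine receptor Xcr1 (−1.72), Clec9a (−1.54), Itgax (−0.82) and again Irf8. MHC class II genes moved with these lists: all 8 lay below 0 (median −1.03, camera adjusted p = 4.4e-12, and adjusted p = 0.27 with an estimated correlation). H2-Ab1 fell over all genes and 7 fell over the list alone, with Cd74 at −1.86, H2-Aa at −1.36 and H2-Eb1 at −1.26. Genes of multipotent and lymphoid-primed progenitors had a median of −0.56 over 13 members (camera adjusted p = 1.1e-05, and adjusted p = 0.27 with an estimated correlation). There, 8 fell and 2 rose over the list alone; the chromatin organizer Satb1 was at −0.83, Dntt and Rag1 stand in the B cell list too, and Cd48, a surface marker of multipotent progenitors, rose by 0.47 over all genes (adjusted p = 0.0493).

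Stem cell genes moved the other way. Of 27 measured LSK stem cell genes 25 lay above 0, with a median of 0.41 (camera adjusted p = 7.8e-12, and adjusted p = 0.27 with an estimated correlation); fry, which tests the list itself, gave an adjusted p of 0.041. Over the list alone 13 rose and over all genes 1, Cd48, which marks progenitors more than the most primitive stem cells. The homeobox gene Meis1 was at 0.96 (SE 0.13, adjusted p = 0.0565), Ctnnal1 at 0.95 and Rbpms at 0.70. Of 17 megakaryocyte genes 16 lay above 0 (median 0.41, camera adjusted p = 6.2e-06, and adjusted p = 0.27 with an estimated correlation), and 6 rose over the list alone, with 0 over all genes. Those were led by the thrombin receptor F2r (1.28), Ppbp (0.95), Itga2b (0.55) and Cd9 (0.90), and without vector replicate 2 the median was 0.24. Of 20 genes of mast cells, basophils and eosinophils, 5 rose and 1 fell over the list alone, and Gzmb rose over all genes (median 0.57, camera adjusted p = 0.0054, and adjusted p = 0.66 with an estimated correlation). Il4 was at 0.91 and Cyp11a1 at 1.65, while Prg2, an eosinophil granule protein, was at −0.99. That call ended without vector replicate 1 (median 0.28) and without BCR-ABL replicate 2 (median 0.37).

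Arachidonate and leukotriene genes had a median of 0.17 over 15 members (camera adjusted p = 0.0052, adjusted p = 0.27 with an estimated correlation, and fry adjusted p = 0.041). Alox5, the lipoxygenase that starts leukotriene synthesis, rose 2.80-fold (log2 change 1.48, SE 0.15, adjusted p = 0.0254), and over the list alone it rose with Pla2g4a (0.68) and Tbxas1 (1.11), 3 genes in all, while Cysltr2 (1.34) did not pass; the call ended without vector replicate 1 (adjusted p = 0.08). In a list of 20 leukemic stem cell regulators, chosen from earlier work of the same field and not independent evidence, Alox5 rose over all genes, and 2 rose and 2 fell over the list alone. These were Alox5 and Il2ra (2.03) against Cd93 (−0.45) and Bcl6 (−0.73), and the list did not pass (median 0.16, camera adjusted p = 0.73). STAT5 and cytokine feedback genes had a median of 0.19 over 20 members (camera adjusted p = 0.0011, and adjusted p = 0.33 with an estimated correlation); 4 rose and 1 fell over the list alone, with 0 over all genes. The signalling inhibitors Socs2 and Cish were at 2.69 (SE 0.47) and 1.02 (SE 0.19), Id1 at 0.52 and Bcl6 at −0.73, and the call ended without BCR-ABL replicate 2 (median 0.16). The 5 study genes passed as a list (median −0.48, camera adjusted p = 0.0052, and adjusted p = 0.33 with an estimated correlation), with Blk, Ebf1 and Pax5 lower over the list alone. Without vector replicate 1 (−0.38) and without BCR-ABL replicate 1 (−0.45) that call ended.

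Another 5 lists were lower by smaller amounts, each losing its call without some array. Interferon response genes had a median of −0.32 (camera adjusted p = 0.00021, and adjusted p = 0.66 with an estimated correlation), with 4 down and 1 up of 23 over the list alone and 0 over all genes; the median was 0.01 without vector replicate 1 and −0.08 without BCR-ABL replicate 1. Its leading members were Gbp3 (−0.84), Irf7 (−0.998), Mx1 (−0.48) and Ifitm3 (0.15). Neutrophil granule genes had a median of −0.24 (camera adjusted p = 0.00074, and adjusted p = 0.66 with an estimated correlation), and 0 of 19 passed over the list alone or over all genes. Fcnb was at −1.11, Elane at −0.96, Prtn3 at −0.65 and Mpo at −0.27, and the median was 0.02 without vector replicate 2, −0.51 without vector replicate 1 and −0.05 without BCR-ABL replicate 1. Erythroid genes had a median of −0.25 (camera adjusted p = 0.0021, and adjusted p = 0.66 with an estimated correlation), which was 0.08 without vector replicate 1 and −0.55 without vector replicate 2. Of 18 erythroid genes, 0 passed over all genes and Nfe2 (0.46) rose over the list alone, with Car1 at −1.15, Ermap at −0.72 and Klf1 at −0.51. MHC class I genes had a median of −0.17 (camera adjusted p = 0.00093, and adjusted p = 0.33 with an estimated correlation), with 0 of 8 past either test and Tap1 at −0.37, Tapbp at −0.34 and Psmb8 at −0.19. That call ended without vector replicate 1 (−0.17), without BCR-ABL replicate 1 (−0.10) and with each array centred on its median (−0.04). G2/M genes had a median of −0.08 (camera adjusted p = 0.0011, and adjusted p = 0.66 with an estimated correlation), with 0 of 29 past either test, Mki67 at −0.26 and Foxm1 at −0.35. Their median turned to 0.07 with each array centred on its median, and was −0.04 without vector replicate 1, −0.02 without BCR-ABL replicate 2, −0.14 without vector replicate 2 and −0.15 without BCR-ABL replicate 1.

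The remaining cell type and quality lists did not pass between BCR-ABL and vector. T and NK cell genes had a median of 0.02 (camera adjusted p = 0.60), although Klrd1, a receptor of NK cells, fell by 1.29 over all genes (adjusted p = 0.0187) at low levels, from 6.92 to 5.63, with Lat at 1.34 (adjusted p = 0.0504), Thy1 at 1.21 and Ncr1 at −0.34. Stromal and endothelial genes had a median of 0.04 (camera adjusted p = 0.49), ribosomal protein genes of 0.01 (0.74) and sex-linked genes of 0.12 (0.51). Stress and dissociation genes had a median of 0.01 and a mean of −0.01 (camera adjusted p = 0.88), with Hspb1 at 0.91 and the metallothioneins Mt2 and Mt1 at −0.99 and −0.81; camera put this list down and fry up. Over all 39 lists, 5 were higher and 11 lower by camera with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.27) and 2 by fry. Without vector replicate 1, camera passed 9.

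**Figure D3:**
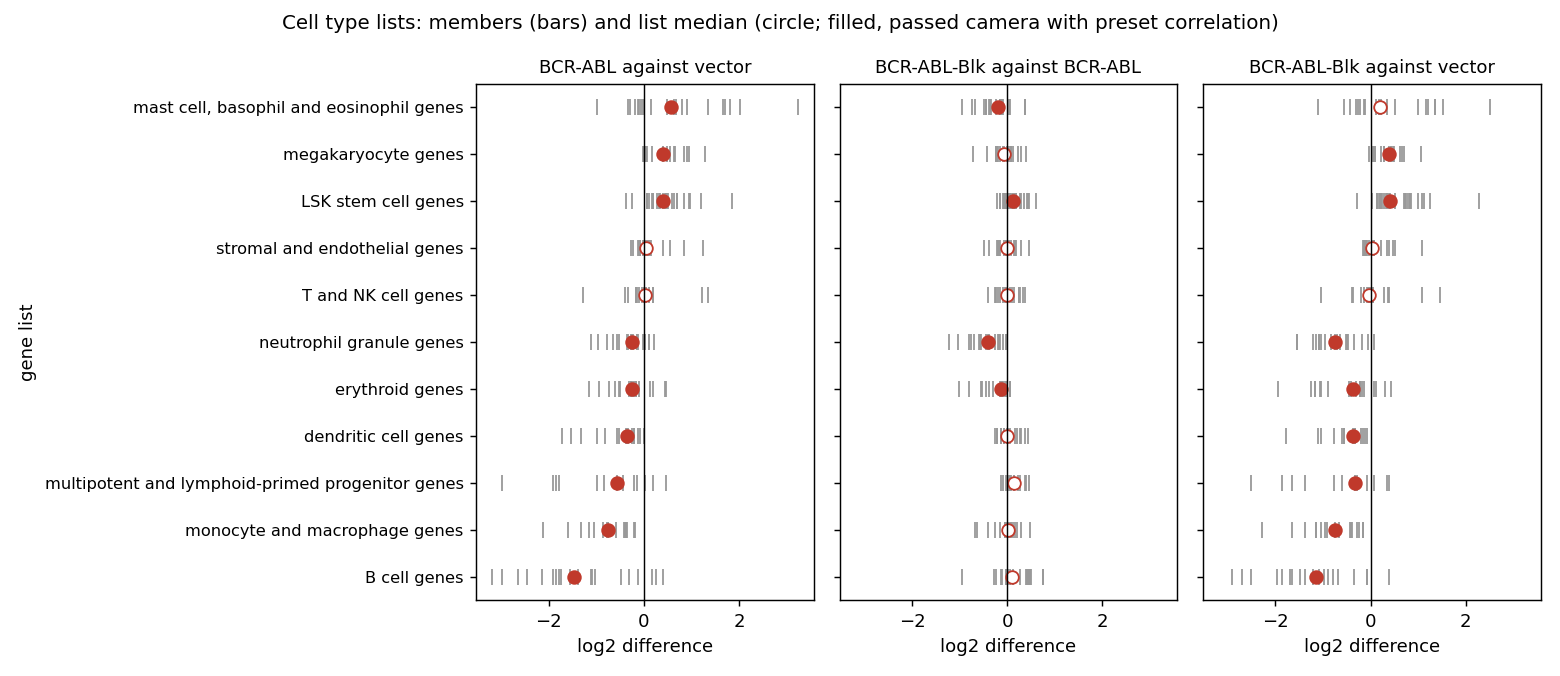
Log2 difference (horizontal axis) of each measured member (grey bars) and the median (circles) of 11 cell type lists in 3 comparisons, filled where camera with the preset correlation passed. B cell genes have the lowest median against vector, at −1.46 for BCR-ABL and −1.15 for BCR-ABL-Blk, while LSK stem cell genes lie above 0 in each comparison.

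The comparison of BCR-ABL-Blk with BCR-ABL asked what added Blk does to cells that carry the oncogene. No single gene passed, so the values below are the nearest to the threshold, each at an adjusted p of 0.999 with 2 arrays per group. Among the genes that the naming rule admits, the lowest unadjusted p values belonged to genes lower with Blk: Il1r2, the decoy receptor of interleukin 1, at −0.79 (SE 0.14), Gldc, the glycine decarboxylase, at −0.998 (SE 0.17), and Khdc1a at −2.22 (SE 0.39). Next came the lectin Clec4d (−1.02), the cytokine Il4 (−0.68), the iron exporter Slc40a1 (−0.73), Ddah1 (−0.76) and Fgl2 (−0.74). On the higher side lay Ufsp1 (0.97, SE 0.21), Fryl (0.79), Rab1b (0.79), Gpatch8 (0.56), Arhgef5 (0.60), Gnrh1 (0.89), Tmem229b (0.69) and Taf1d (0.17), of which Taf1d was at −0.02 with each array centred on its median. By limma, 0 genes were higher and 0 lower at an adjusted p under 0.05, or under 0.10. At an unadjusted p under 0.05 there were 790 genes, 293 higher and 497 lower, fewer than the 997 that chance gives. Without BCR-ABL-Blk replicate 1, 2 genes were lower, Khdc1a (−2.92, adjusted p = 0.0404) and 3830403N18Rik (−2.31, adjusted p = 0.0404), the latter named after its values were seen. Without normalization between arrays 66 were higher and 13 lower.

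Neutrophil granule genes stood out among the lists in BCR-ABL-Blk against BCR-ABL cells. All 19 lay below 0, with a median of −0.40 (camera adjusted p = 1.7e-06, adjusted p = 0.82 with an estimated correlation, and fry adjusted p = 0.83), though 0 passed over all genes or over the list alone. Their estimated correlation was 0.48, so the members move together and the 19 signs are not independent. Lipocalin 2 (Lcn2) was at −1.23 (SE 0.29), the cathelicidin Camp at −0.81, and S100a8 and S100a9 at −0.56 and −0.38. The median was −0.24 without BCR-ABL-Blk replicate 2, and −0.24 without normalization between arrays, where all genes shifted by 0.255. LSK stem cell genes were higher by a median of 0.12 (camera adjusted p = 0.0073, and adjusted p = 0.82 with an estimated correlation), with the receptors Tek at 0.60 and Tie1 at 0.35, Gfi1b at 0.45 and Vwf at 0.30. That median was 0.02 with each array centred on its median, and the call ended without BCR-ABL replicate 1 (0.08). Of the 8 lists that passed, none held a gene past the threshold over all genes, and Il4 alone, in the list of mast cells, basophils and eosinophils, was lower when adjusted over the list alone (adjusted p = 0.0167).

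The other 6 lists that passed had small medians, and each lost its call or turned its sign without some array. Genes of mast cells, basophils and eosinophils were at −0.19 (camera adjusted p = 0.024, and adjusted p = 0.85 with an estimated correlation), with Gzmb at −0.75, Hdc at −0.95 and Cyp11a1 at −0.44. The sign of that list turned to 0.15 without BCR-ABL-Blk replicate 2; the median was −0.50 without replicate 1, −0.37 without BCR-ABL replicate 1, and the call ended without BCR-ABL replicate 2 (−0.14). Erythroid genes were at −0.13 (camera adjusted p = 0.014, and adjusted p = 0.85 with an estimated correlation), with Klf1 at −0.54, Kel at −0.56 and Car1 at −0.79; that call ended without BCR-ABL replicate 1 (−0.10) and without BCR-ABL-Blk replicate 2 (−0.10), and the median was −0.20 without BCR-ABL-Blk replicate 1. Stress and dissociation genes, a sign of handling, were at −0.21 (camera adjusted p = 0.024, and adjusted p = 0.82 with an estimated correlation), with Mt1 at −0.78, Mt2 at −0.61 and Hspb1 at −0.39. Without BCR-ABL replicate 1 (−0.12) and without BCR-ABL-Blk replicate 2 (−0.08) that call ended. Adhesion and homing genes were at −0.11 (camera adjusted p = 0.028, and adjusted p = 0.82 with an estimated correlation), with the chemokine receptors Ccr1 at −0.89 and Ccr2 at −0.63. STAT5 and cytokine feedback genes were at −0.07 (camera adjusted p = 0.039, and adjusted p = 0.82 with an estimated correlation), with Spry2 at −0.48, Id1 at −0.37, Osm at −0.41 and Bcl6 at −0.35. Both of these lists lost their call without BCR-ABL replicate 2 (−0.09 and −0.04), without BCR-ABL-Blk replicate 1 (−0.14 and −0.09) and without BCR-ABL-Blk replicate 2 (−0.08 for each). G2/M genes were at 0.07 (camera adjusted p = 0.017, and adjusted p = 0.89 with an estimated correlation), with Kif23 at 0.25, Foxm1 at 0.23 and Mki67 at 0.14. Their median turned to −0.06 with each array centred on its median and to −0.02 without BCR-ABL replicate 2, was 0.02 without BCR-ABL-Blk replicate 1, and was 0.15 and 0.16 without the partners of those arrays. Without normalization between arrays the erythroid (0.15), adhesion (0.14), STAT5 (0.14), stress (0.07) and mast cell (0.04) medians were above 0, yet below the shift of 0.255 of all genes.

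Of the 16 lists that passed between BCR-ABL and vector, 6 passed between BCR-ABL-Blk and BCR-ABL too, those of neutrophil, LSK stem cell, erythroid, G2/M, mast cell and STAT5 genes. Among those that did not pass here, the medians were 0.09 for B cell genes (camera adjusted p = 0.19), 0.01 for monocyte and macrophage genes (0.93), 0.01 for dendritic cell genes (0.57), 0.15 for multipotent and lymphoid-primed progenitor genes (0.093), 0.16 for MHC class II genes (0.058) and −0.07 for megakaryocyte genes (0.97). Within the B cell list, 10 early B-lineage genes had a median of 0.42 (−2.03 for BCR-ABL against vector) and 9 genes of committed precursors 0.44 (−1.74), while Ebf1 and Pax5, members of both, were at −0.27 and −0.10. These sublists were drawn up after their fall was seen on the same BCR-ABL arrays, which by itself favours a rise here, and were not tested. The median B cell gene differed by 0.37 between the BCR-ABL-Blk replicates. T and NK cell genes had a median of 0.00 (camera adjusted p = 0.59), stromal and endothelial genes of −0.01 (0.97), ribosomal protein genes of −0.02 (0.45) and sex-linked genes of −0.07 (0.52). In total 2 lists were higher and 6 lower by camera with the preset correlation, 0 with an estimated correlation and 0 by fry. Camera passed 5 lists without BCR-ABL replicate 1, 4 without BCR-ABL-Blk replicate 2 and 14 without normalization between arrays.

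The comparison of BCR-ABL-Blk with vector asked what still separates the cells with both genes from control LSK cells. Akr1c12 again rose most, 21.0-fold (log2 change 4.39, SE 0.13, adjusted p = 4.38e-05), to 11.3 ± 0.04 (SD, n = 2), from the same low vector mean of 6.92, and its paralog Akr1c13 rose by 2.65 (adjusted p = 0.00173). Ndrg2 rose 5.44-fold (log2 change 2.44, SE 0.15, adjusted p = 0.00241). Ncam2 rose by 2.74, Gzmb by 2.503, Itm2a by 2.32, Enah by 2.31 and Timp3, an inhibitor of metalloproteinases, by 2.02; of these, Ncam2, Gzmb, Itm2a and Timp3 lay below the median level of named genes in vector cells. Among the genes that fell, Cybb decreased by 1.45 (SE 0.15, adjusted p = 0.0383), Ccr2, the chemokine receptor of inflammatory monocytes, by 1.38, Fgl2 by 1.25 and H2-Ab1 by 1.23. Slc40a1, the iron exporter of macrophages and erythroid cells, fell by 1.39, Tifab by 1.103 and Cst3 by 0.42, while Naaa (−1.25, adjusted p = 0.0517) did not pass. By the naming rule, the arrays of the groups did not overlap for any of these genes, as for 37.2% of all genes.

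In total 19 genes were higher and 9 lower in BCR-ABL-Blk than in vector cells at an adjusted p under 0.05, with 1878 at an unadjusted p under 0.05. After cyclic loess between arrays, 6 were higher and 0 lower. With an array left out the genes that passed changed too, so a count near that of the main setting does not mean the same genes. The counts were 338 higher and 220 lower without vector replicate 1, 57 and 167 without vector replicate 2, 4 and 0 without either BCR-ABL array, 10 and 0 without BCR-ABL-Blk replicate 1, and 20 and 0 without BCR-ABL-Blk replicate 2. Without either BCR-ABL array those 4 were Akr1c12, Akr1c13, Ndrg2 and Ifitm1, an interferon-induced membrane protein named after its values were seen (0.65 and 0.64 without BCR-ABL replicates 1 and 2).

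LSK stem cell genes were higher as a group in BCR-ABL-Blk than in vector cells: 26 of 27 lay above 0, with a median of 0.40 (camera adjusted p = 2.4e-17, adjusted p = 0.15 with an estimated correlation, and fry adjusted p = 0.029). Over the list alone 15 rose, and over all genes Meis1 rose 2.12-fold (log2 change 1.08, SE 0.13, adjusted p = 0.049). Mycn was at 1.13, the endothelial receptor Tie1 at 0.83 and Cd48 at 0.38, each at an adjusted p of 0.0714. Megakaryocyte genes had a median of 0.40 (camera adjusted p = 2.8e-06, and adjusted p = 0.34 with an estimated correlation); 3 of 17 rose over the list alone and 0 over all genes, with F2r at 1.07, the clotting factor Vwf at 0.71 and Itga2b at 0.48, and the median was 0.11 without vector replicate 2. Neutrophil granule genes were lower, 18 of 19 below 0 with a median of −0.75 (camera adjusted p = 7.8e-12, and adjusted p = 0.42 with an estimated correlation). Over that list alone 12 fell and over all genes 0; neutrophil elastase (Elane) was at −1.56, haptoglobin (Hp) at −1.54, Lcn2 at −1.21 and S100a8 at −0.70. Monocyte and macrophage genes had a median of −0.75 (camera adjusted p = 7.8e-12, and adjusted p = 0.34 with an estimated correlation), which was −0.42 without vector replicate 1. Of these, 8 of 17 fell over the list alone and Ccr2 fell over all genes, with F13a1 at −2.27, Cd68 at −1.15 and Irf8 at −1.04.

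B cell genes had a median of −1.15 (camera adjusted p = 1.4e-11, and adjusted p = 0.46 with an estimated correlation), which was −0.66 without vector replicate 1 and −1.78 without vector replicate 2. Of these, 13 of 20 fell over the list alone and 0 over all genes, with Blnk at −2.71, Dntt at −1.39 and the receptor chain Cd79b at −1.21. Dendritic cell genes had a median of −0.36 (camera adjusted p = 3.2e-10, and adjusted p = 0.34 with an estimated correlation); 3 of 16 fell over the list alone, Xcr1 (−1.78), Clec9a (−1.11) and Irf8, while Cd7 (−0.55) did not pass. MHC class II genes had a median of −0.84 (camera adjusted p = 8.1e-09, and adjusted p = 0.42 with an estimated correlation), with 6 of 8 down over the list alone, H2-Ab1 down over all genes, Cd74 at −1.44 and H2-Eb1 at −1.33. Erythroid genes had a median of −0.36 (camera adjusted p = 6.9e-06, and adjusted p = 0.51 with an estimated correlation); 7 fell and 1 rose of 18 over the list alone, with Klf1, the erythroid transcription factor, at −1.05, Car1 at −1.94, Ermap at −1.16 and Kel at −1.16. That call ended without vector replicate 1 (−0.13), and the median was −0.70 without vector replicate 2. Multipotent and lymphoid-primed progenitor genes had a median of −0.33 (camera adjusted p = 0.0023, and adjusted p = 0.42 with an estimated correlation), with 5 down and 2 up of 13 over the list alone, Satb1 at −0.77 and Cd34 at 0.36; with dim genes left out this call ended (adjusted p = 0.073).

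Another 5 lists passed by less, each losing its call without some array. Interferon response genes were at −0.14 (camera adjusted p = 0.027, and adjusted p = 0.73 with an estimated correlation), with Gbp3 at −0.83, Mx1 at −0.53, Zbp1 at −0.80 and Ifitm3 at 0.16. Their median turned to 0.11 without vector replicate 1, was −0.29 without vector replicate 2, was 0.01 without normalization between arrays, and the call ended without BCR-ABL-Blk replicate 1 (−0.12). Unfolded protein response genes were at −0.14 (camera adjusted p = 0.027, and adjusted p = 0.42 with an estimated correlation), although Sesn2 (0.61) rose over the list alone, with Hspa5 at −0.14, Sdf2l1 at −0.54 and Calr at −0.19. That call ended without vector replicate 2 (−0.07) and without BCR-ABL-Blk replicate 2 (−0.13). Adhesion and homing genes were at −0.13 (camera adjusted p = 0.032, and adjusted p = 0.42 with an estimated correlation), with 3 down and 1 up of 17 over the list alone, Ccr2 down over all genes, the integrins Itgam and Itgb2 at −0.61 each and Itga6 at 0.49. The call ended without either vector array (−0.12 and −0.10) and without either BCR-ABL-Blk array (−0.11 and −0.14). The 5 study genes were at −0.07, with a mean of −0.90 (camera adjusted p = 0.032, and adjusted p = 0.45 with an estimated correlation), and Ebf1 and Pax5 were lower over the list alone; the call ended without vector replicate 1 (−0.14) and without BCR-ABL-Blk replicate 2 (−0.10), and the median was −0.21 without vector replicate 2 and −0.12 without BCR-ABL-Blk replicate 1. MHC class I genes were at −0.11 (camera adjusted p = 0.048, and adjusted p = 0.52 with an estimated correlation), with 0 of 8 past either test and Psmb8 at −0.22, Tap1 at −0.33 and Tapbp at −0.30. That call ended without vector replicate 1 (−0.12) and without BCR-ABL-Blk replicate 1 (−0.06), and the median was −0.17 without BCR-ABL-Blk replicate 2. Without normalization between arrays the median of the adhesion list was 0.03, of the unfolded protein response 0.02, of the study genes 0.08 and of MHC class I 0.07, each below the shift of 0.15 of all genes.

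Lists that did not pass between BCR-ABL-Blk and vector are given as values. Genes of mast cells, basophils and eosinophils had a median of 0.20 (camera adjusted p = 0.22), with Gzmb up over all genes, 3 up and 1 down over the list alone, the chymase Cma1 at 1.35, Cyp11a1 at 1.21 and Prg2 at −1.11. T and NK cell genes had a median of −0.03 (camera adjusted p = 0.92), with Klrd1 down by 1.03 over all genes (log2 change −1.03, from 6.92 to 5.89, again at low levels), Lat at 1.09, Thy1 at 1.46 and Cd8a at −0.39. Stromal and endothelial genes had a median of 0.03 (camera adjusted p = 0.41), ribosomal protein genes of 0.00 with a mean of −0.01 (0.72), and sex-linked genes of 0.00 (0.92). Stress and dissociation genes had a median of 0.01 but a mean of −0.25 (camera adjusted p = 0.22). By camera with the preset correlation 2 lists were higher and 12 lower, 0 passed with an estimated correlation and 1 by fry, and camera passed 9 without vector replicate 1.

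Both groups with BCR-ABL were then compared through the vector arrays they share. In the same direction, 14 genes were higher and 5 lower in both, 19 in all, among them Akr1c12, Akr1c13, Gzmb, Ncam2, Enah, Itm2a, H2-Ab1, Cybb, Tifab and Cst3. Independent lists of these sizes would share 0.0229 and 0.00226 genes. The 19 were 65.5% of the genes changed by BCR-ABL, against 83.4% in simulations in which BCR-ABL keeps its effect on 112 genes and Blk has none (95% range 73.5 to 93.7). Those simulations called 69.45 genes and shared 41.97 higher and 15.84 lower on average, more than the data did, so the shares are not closely comparable. Across genes the log2 changes correlated at r = 0.793, against 0.637 in those simulations and 0.499 in simulations without any effect that share the vector arrays. Against the latter they had the same sign more often, for 72.6% of genes against 66.7%, and a covariance of 0.0555 against 0.0164. The vector group split in 2 would give 1 array each, so part of the excess may come from the shared vector arrays. The simulations also gave every group the same variance per gene. Array weights, lower for more variable arrays, were 0.736 for vector, 1.205 for BCR-ABL and 1.127 for BCR-ABL-Blk arrays. A more variable shared group raises these values without any effect, so the simulated values are likely too low a yardstick. The 19 became 351 without vector replicate 1, 156 without vector replicate 2, 1 without either BCR-ABL array and 6 without BCR-ABL-Blk replicate 1.

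The design also asks whether changes with BCR-ABL moved back when Blk was added, and by limma 0 genes passed in both comparisons with opposite signs. Among the 29 genes changed by BCR-ABL, 7 (24.1%) had an unadjusted p under 0.05 toward vector, against 8.99% of the called genes in simulations in which Blk has no effect (95% range 3.38 to 16.4), which called 69.45 genes on average and so do not match the data in size. Adjusted over these 29 genes alone, 4 moved back and 0 moved on: Gldc regained 69.7% of its change, Khdc1a 62.3%, Il1r2 62.1% and Perp, a p53 target, 44.8%; these 4 are named after their values were seen. Their vector means (6.49, 5.30, 6.80 and 7.28) lay below the median level of named genes, so these shares are those of the measured signal and could shift with the background, which was not measured. Akr1c12 regained 0.3%, Akr1c13 1.8% and Gzmb 23.0%. In BCR-ABL-Blk cells the 2 arrays lay far apart for Khdc1a (6.645 ± 0.983) and Gzmb (9.722 ± 0.757, mean ± SD). The shares of these genes therefore differ widely between the arrays. The median gene regained 11.4%, with 20 under 20% and 3 over 50%, where the simulations without a Blk effect gave a median of 2.45% (95% range −1.03 to 6.09). The sign was opposite for 25 of the 29, or 86.2%, against 58.2% in those simulations (range 45.9 to 69.5). The genes were chosen for their change on the same BCR-ABL arrays, so these shares are not independent evidence of a Blk effect. The simulations took as true the measured changes of genes picked by their p-value, which such a choice tends to inflate. Their movement back is therefore likely too low, and their ranges too narrow a yardstick for the data. Over all genes the covariance of the changes was −0.0133 against −0.0164 in simulations without any effect. The correlation was −0.298, against −0.50 there and −0.425 in simulations without a Blk effect. Opposite movement over all genes thus did not exceed that in these simulations. They gave every group the same variance per gene, while array weights were 1.205 for BCR-ABL and 0.736 for vector arrays. Whether the movement was weaker than shared BCR-ABL arrays give by themselves therefore cannot be told. Without BCR-ABL-Blk replicate 1, 1 gene moved back over all genes, Khdc1a, and without normalization between arrays 16 did.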

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

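Of the alternatives below, the values without normalization between arrays, and the other scalings and left-out arrays for gene lists, were chosen after seeing the data. Of the values for single genes under these alternatives, 802 kept direction and side of the threshold, 48 passed newly, 146 no longer passed and 28 changed sign. Of those for lists, 358 kept the direction of the test and its side of the threshold, 134 no longer passed and 2 changed the direction of the test, which compares a list with the other genes. The sign of the list median itself turned in 18, of which 10 were without normalization between arrays, where all genes shift, 6 with an array left out and 2 with each array centred. The cause was not tested unless stated. With no detection calls used, how many genes lay near background is not known.

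Without normalization between arrays, BCR-ABL against vector gave 176 higher and 225 lower, BCR-ABL-Blk against BCR-ABL 66 and 13 with 14 lists, and BCR-ABL-Blk against vector 562 and 170; 16 genes moved back and 283 changed the same way in both BCR-ABL groups. Cyclic loess gave 10 lower for BCR-ABL against vector, 6 higher and 0 lower for BCR-ABL-Blk against vector, and 6 in the same direction. With dim genes left out, so that fewer genes were tested, the counts were 38 higher and 15 lower, 43 and 28, and 37 in the same direction, with 5 lists for BCR-ABL-Blk against BCR-ABL. Averaging probe sets gave 10 lower for BCR-ABL. Centring each array on its median gave 5 lower for BCR-ABL, of which 2 were among the 5 of the main setting. With only the 4 arrays compared, which lowers the residual degrees of freedom, BCR-ABL had 2 lower, BCR-ABL-Blk 4 higher and 0 lower against vector, and 4 in the same direction. No intensity trend gave 12 and 3, 4 and 0, and 4 in the same direction. Array weights gave 12 higher and 2 lower for BCR-ABL-Blk against vector, with weights of 0.736 for vector, 1.205 for BCR-ABL and 1.127 for BCR-ABL-Blk arrays. At an adjusted p under 0.10 the counts were 82 and 30, 80 and 57, and 68 in the same direction. With an estimated correlation camera passed 0, 0 and 0 lists, and fry 2, 0 and 1, in the order in which the comparisons are given above.

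Samples with the same replicate number deviated from their group means with correlations of −0.062, 0.084 and 0.033, so no pairing was seen over all genes. This cannot exclude a shared batch that touches some genes. Replicates 1 of BCR-ABL and BCR-ABL-Blk correlated at r = 0.995, against 0.994 and 0.992 between the replicates of these groups. With the replicate block, genes lower in BCR-ABL-Blk than in vector went from 9 to 5, and no other count moved by over 1.5 times. The genes behind the counts changed more. Of 6 lower in BCR-ABL than in vector, 3 were among those of the main setting, and of 18 higher in BCR-ABL-Blk, 12 were.

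Leaving out each array in turn gave 1 to 345 genes higher and 0 to 157 lower in BCR-ABL, and 4 to 338 higher and 0 to 220 lower in BCR-ABL-Blk, against vector. BCR-ABL-Blk against BCR-ABL gave 0 higher and 0 to 2 lower, 0 to 1 moved back, and 1 to 351 changed in the same direction. Lists numbered 9 to 17, 4 to 11 and 9 to 15. Without vector replicate 1 and without replicate 2, 55 of the genes higher and 28 of those lower in BCR-ABL were the same.

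Given next are the 28 values of single genes whose sign turned and the 2 of lists whose test turned direction; ranges are the lowest and highest value with an array left out. For BCR-ABL against vector, Myc was −0.003 with cyclic loess and −0.064 to 0.084 with an array left out. Cdkn1b was −0.058 with averaged probe sets, and −0.17 to 0.321 with an array left out.

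For BCR-ABL-Blk against vector, Blk was 0.08 without normalization and −0.169 to 0.026 with an array left out. Myc was 0.075 without normalization and −0.139 to 0.01 with an array left out, and Cdkn1b −0.21 to 0.28. Abl1 was −0.136 to 0.171 with an array left out. Bcr was −0.008 with averaged probe sets and −0.031 to 0.092 with an array left out. The interferon response genes ranged from −0.29 to 0.113.

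For BCR-ABL-Blk against BCR-ABL, Taf1d was −0.02 with centred arrays. Without normalization Pax5 was 0.17, Myc 0.07 and Cdkn1b 0.165, and with averaged probe sets Cdkn1b was 0.156. With an array left out Pax5 ranged from −0.45 to 0.233, Ebf1 from −0.95 to 0.387 and Cdkn1b from −0.20 to 0.117. The mast cell, basophil and eosinophil genes ranged from −0.50 to 0.153, the latter without BCR-ABL-Blk replicate 2.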

Other observations

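All tests of explanations below were chosen after the results they address were seen, and their limits were revised after their values were seen.

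Several pathways that BCR-ABL signalling is known for did not pass camera between BCR-ABL and vector cells. Camera asks for a shift in 1 direction, so this does not show that their genes were unchanged. The mixed test of fry lets members move either way. It gave an adjusted p of 0.0029 for Wnt and 0.035 for TGF-beta and FoxO genes, and 0.05 to 0.63 for the other pathways listed next. It also gave 0.0039 for sex-linked genes, a quality list. MYC target genes had a median of 0.03 over 24 members (camera adjusted p = 0.28), G1/S genes of 0.00 over 29 (0.58), glycolysis genes of 0.07 (0.22), oxidative phosphorylation genes of 0.04 (0.65) and cholesterol synthesis genes of 0.14 (0.18). Apoptosis regulators were at −0.02 (camera adjusted p = 0.54), hypoxia genes at 0.12 (0.14), Wnt and beta-catenin genes at 0.03 with a mean of −0.02 (0.90) and TGF-beta and FoxO genes at 0.08 (0.54), for which camera and the mean (−0.07) pointed down. The 13768 probe sets without a single gene symbol held 0 past the limma threshold in each comparison, with 651, 544 and 803 at an unadjusted p under 0.05.

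Src family kinases did not all move one way in BCR-ABL against vector cells. Over the list alone Fyn (0.71, SE 0.16) and Yes1 (0.38, SE 0.11) rose and Blk (−0.48, SE 0.11) fell, with 0 of 5 over all genes at a limma adjusted p under 0.05; Yes1 (5.17 to 5.55) and Blk (7.05 to 6.57) read low, and signal over background was not measured. As a list they did not pass (median 0.12, camera adjusted p = 0.51). Among 17 adhesion and homing genes, which did not pass in this comparison either (median −0.11, camera adjusted p = 0.53), Itga6 (0.52) and Cdh2 (0.40) rose and Ccr2 (−0.75) fell over the list alone.

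The B cell genes were lower in BCR-ABL than in vector cells, and cells of the B lineage in the vector sort are a candidate explanation. Mature B cells are argued against, also by the gate, which removes lineage-positive cells: 7 mature B cell genes, 3 of them in the B cell list, had a median change of 0.01 (SE between members 0.05), with a highest vector mean of 8.37. Committed B-lineage precursors remain open: their 9 measured genes, all in the B cell list, had a median of −1.74 (SE 0.25), with a highest vector mean of 12.1, although the same gate would remove precursors that carry lineage markers or lack c-Kit or Sca-1. Whether vector replicate 1 alone makes the pattern cannot be told apart: without it the median was −0.659 and vector replicate 2 (0.132 from the mean of all arrays) lay above the 4 arrays with BCR-ABL (−0.709 to −0.221), but 1 vector array then remains and its spread is unknown. An effect of BCR-ABL on lymphoid progenitors, which the design names, was not tested and stays open.

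The LSK stem cell genes were higher in BCR-ABL than in vector cells by a median of 0.41. Loss of lymphoid cells from the gate could raise them in proportion. Between the vector arrays, which differ by 1.37 in B cell genes, they differed by 0.05 (SE between members 0.073). A value of −0.39 would be needed if the log2 changes of both lists kept their proportion. This is 1 pair of arrays, which also differ by −0.607 in neutrophil granule and 0.606 in erythroid genes. It therefore cannot decide whether loss of lymphoid cells raised the list. Scaling is argued against as the whole cause, since the nearest median to 0 among 3 other scalings was 0.285, where all genes shifted by −0.11, and the list lay 0.395 above all genes under each. Centring on the median and no normalization differ only by a constant per array, so relative to all genes they are the same test. A change of cell state or of makeup with BCR-ABL stays a hypothesis, and camera with an estimated correlation did not pass (adjusted p = 0.27). That estimate was 0.02, near the preset 0.01, so a high correlation does not explain the lost call.

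The neutrophil granule genes were lower in BCR-ABL-Blk than in BCR-ABL cells by a median of −0.40. Scaling is argued against as the whole cause: among 3 other scalings the median nearest to 0 was −0.235, where all genes shifted by 0.255, and relative to all genes the list stood at −0.384 to −0.49, against SDs of its median between replicates of 0.15 in BCR-ABL and 0.20 in BCR-ABL-Blk. Between the vector replicates, outside this comparison, that SD was 0.43, so the list can vary as much between arrays of a group. Centring and no normalization both gave −0.49, since they differ only by a constant per array. Whether BCR-ABL-Blk replicate 2 alone makes the pattern cannot be told apart, since without it the median was −0.241 and 1 array of that group remains, whose spread is unknown. Both BCR-ABL-Blk arrays (−0.22 and −0.51 from the mean of all arrays) lay below both BCR-ABL arrays (−0.057 and 0.209). An effect of Blk, which the design names, may lie behind it but was not tested and stays open.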
